A study of Mus musculus with 12 samples.

How the data were processed

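RNA from 6 isolated populations of the mouse small intestine, each from 2 biological replicates, was measured on 12 Affymetrix expression arrays, with 2000 cells per sample and 22 amplification cycles per the labels' protocols. The deposited values are log2 expression values per probe set, which the authors made with RMA per the submitters' processing notes; the RMA version and settings are not given in the sources used here. The labels give the population (Mex3a high, low or negative with Lgr5 high or low), the biological replicate (MR793 or MR820) and the array strip (3 strips), and the 12 columns of the deposited table were joined to the samples by their names, with 0 columns left over. The deposited values were used as they are, and no raw intensities were reprocessed.

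The table holds 45141 probe sets, of which 29449 are listed in the probe table used here, 28898 with 1 gene and 551 with several; 15692 are not listed and were not analysed here, and 104 are controls. Gene names are those of the probe table, matched for 28689 probe sets by gene identifier to a mouse gene table, which updated 0 names. For each gene the single-gene probe set with the highest mean over the 12 arrays was used, which gives 17097 genes, 7180 of them with several probe sets. A probe set without signal still has an RMA value, so differences between dim genes are compressed.

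Each gene was fitted with limma as 6 population means without a block, with eBayes and a mean-variance trend (6 residual and 3.44 prior degrees of freedom), and p values were adjusted by the Benjamini-Hochberg method over the 17097 genes of each comparison. A gene was called at an adjusted p under 0.05. The 8 comparisons are the 3 pairs of Mex3a gates within Lgr5-high and within Lgr5-low cells, Lgr5-high against Lgr5-low averaged over the Mex3a gates, and the difference of the Mex3a-high against Mex3a-negative change between the Lgr5 gates. The replicate of the labels pairs the populations. Checked by correlating the replicate differences of each pair of populations, 14 of 15 pairs lay over 0.1 (lowest -0.115, median 0.382, highest 0.566). Without the Mex3a-high Lgr5-high array of MR793 all 10 pairs lay at 0.374 to 0.566. The main values come from the fit without a block, which does not use this pairing. Counts from the fit with the replicate as a block are given among the alternatives, and its p values for some genes only. In changes per replicate, MR793 or MR820 stands for the difference of 2 arrays of that replicate in the pairs of Mex3a gates, of the means of 3 arrays each between the Lgr5 gates, and for a contrast of 4 arrays in the difference between gates. SE is the moderated standard error of limma, and SD the spread of n = 2 arrays.

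Gene lists were written from general knowledge before the data were examined, and are given with the number of genes measured: intestinal stem cell (27 of 30), Wnt target (18 of 20), reserve stem cell (10 of 10), mitosis (29 of 30), DNA replication (29 of 30), CDK inhibitor (11 of 11), ribosome biogenesis (28 of 30), mitochondrial respiration (28 of 31), fatty acid oxidation and PPAR target (21 of 25), secretory progenitor (14 of 15), Notch pathway (14 of 15), Paneth cell (10 of 20), goblet cell (19 of 20), enteroendocrine cell (26 of 30), tuft cell (17 of 20), enterocyte (26 of 30), immune cell (20 of 20), mesenchymal and endothelial cell (18 of 20), red blood cell (6 of 10), and immediate early and dissociation response (18 of 20). Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison (160 tests), and again with the correlation estimated from the residuals. The preset value treats members as almost independent, so both p values are given. The lists called with an estimated correlation are enterocyte and Paneth cell (Mex3a-low against -negative, Lgr5-high gate); enteroendocrine, tuft, Paneth cell and secretory progenitor (Mex3a-high against -negative and Mex3a-low against -negative, Lgr5-low gate); enteroendocrine and tuft cell (Mex3a-high against -low, Lgr5-low gate, and the difference between the gates); and Wnt target, goblet, enteroendocrine and tuft cell (between the Lgr5 gates). "Adjusted over the list alone" means the Benjamini-Hochberg method over the members of a list.

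Genes named in the text were chosen by a rule fixed before the data were examined: Mex3a and Lgr5 in every comparison; of the called genes with the same sign in both replicates, the 10 with the largest positive and the 10 with the largest negative change in the Mex3a-high against -negative (each gate) and Lgr5 comparisons and 4 each way in the others, gene models passed over; and from each list up to 4 members with the smallest p, with every member needed for a count of 5 or fewer. Genes named outside this rule are said to be so.

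The alternatives tried were the replicate as a block, the strip as a block, both as blocks, quantile normalization again, arrays centred on a common median, the dimmest 40% of genes left out, the mean of all probe sets of a gene, no variance trend, the arrays of a single Lgr5 gate alone, each array left out in turn, and for the lists an estimated correlation. With an array left out its population has 1 array, which is assumed to vary like the others. Camera without the Mex3a-high Lgr5-high array of MR793 was added after that array was seen to stand apart. The MR793 arrays of the Lgr5-high gate lie on strip 1 and those of the Lgr5-low gate on strip 3; of MR820, Mex3a-low Lgr5-high lies on strip 1, Mex3a-negative Lgr5-low on strip 3 and the other 4 on strip 2. Within-strip values use the pairs that share a strip.

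Simulated data with 200 changed genes of 17097 were built on the fitted spread of these arrays. Their noise was independent between genes and arrays, without replicate or strip differences or an array that stands apart. They therefore do not give the rate of false calls on the real arrays. The pipeline was tested on these data. It recovered 42% of changes of log2 1 and 84% of changes of log2 2, with 4 false among 130 calls and 0 calls when nothing was changed; without the array that stood apart it recovered 80% and 98%, with 9 false among 187 calls. The work used R 4.3.3, limma 3.58.1 and the package data.table (version 1.17.8), and for figures Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.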

Results

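Cells of the mouse small intestine were isolated as 6 populations by their level of Mex3a (high, low or negative) and of Lgr5 (high or low), called gates here. Mex3a encodes an RNA-binding protein and Lgr5 a receptor that marks the stem cells of the crypt base. Each population came from 2 biological replicates, MR793 and MR820, so that the 12 arrays give n = 2 per population, a number that limits the precision of every comparison. The Mex3a gates were compared in pairs within Lgr5-high and within Lgr5-low cells, which asks how cells of different Mex3a level differ at a given Lgr5 level. Lgr5-high cells were also compared with Lgr5-low cells over the 3 Mex3a gates. The Mex3a-high Lgr5-high array of MR793 stood apart: its correlation with the other arrays was 0.896 to 0.916, against 0.971 to 0.996 among the other 11. Without it the median residual SD of a gene was 0.116 log2 instead of 0.220, so counts are also given without this array.

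Lgr5 itself separated the Lgr5 gates and the Mex3a probe sets did not separate the Mex3a gates. Lgr5 averaged 9.60 ± 0.86 (mean ± SD, RMA log2, n = 2) in Mex3a-high, 10.13 ± 0.12 in Mex3a-low and 10.02 ± 0.08 in Mex3a-negative cells of the Lgr5-high gate. In the Lgr5-low gate it averaged 7.83 ± 0.32, 7.26 ± 0.18 and 6.81 ± 0.62 in the same order. Lgr5 differed between Mex3a-high and Mex3a-negative cells by -0.41 ± 0.40 (log2 difference ± SE, limma adjusted p = 0.569) in the Lgr5-high gate and by 1.02 ± 0.40 (adjusted p = 0.571) in the Lgr5-low gate. In the Lgr5-high gate this was -1.08 in MR793 and 0.25 in MR820, and 0.19 without the array that stood apart. In the Lgr5-low gate it was 1.68 and 0.36. Mex3a averaged 6.09 ± 0.36, 5.71 ± 0.11 and 5.81 ± 0.14 in the Lgr5-high gate and 5.64 ± 0.10, 5.56 ± 0.11 and 5.52 ± 0.11 in the Lgr5-low gate. Between Mex3a-high and Mex3a-negative cells Mex3a differed by 0.29 ± 0.19 (adjusted p = 0.505) among Lgr5-high and by 0.12 ± 0.19 (adjusted p = 1.00) among Lgr5-low cells. In MR793 and MR820 these were 0.64 and -0.07, with 0.03 without the array that stood apart, and 0.27 and -0.03. Another Mex3a probe set, with levels of 5.01 to 6.37, differed by 0.55 (0.81 in MR793, 0.29 in MR820) and by -0.04 in these comparisons. Both probe sets lie near the median of all probe sets of an array (5.83 to 6.04), and what was used to isolate cells by Mex3a level is not stated in the labels.

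Among Lgr5-high cells, genes of tuft cells, the chemosensory secretory cells of the gut, were among those with the smallest p values between Mex3a-high and Mex3a-negative cells. The tuft cell kinase gene Dclk1 averaged 8.06 ± 0.09 in Mex3a-high and 5.07 ± 0.04 in Mex3a-negative cells, a difference of 2.99 ± 0.32 (3.02 in MR793, 2.95 in MR820). Sh2d6, another tuft cell gene, differed by 3.43 ± 0.38 (3.68 and 3.19). Avil, which encodes the actin-binding protein advillin, differed by 2.05 ± 0.28 (2.21 and 1.90) and the cation channel gene Trpm5 by 2.33 ± 0.38 (2.43 and 2.23). Neurog3, the transcription factor gene that enteroendocrine cells require, differed by 1.62 ± 0.35 (1.36 and 1.88), and the granin gene Chgb by 3.52 ± 0.81 (5.16 and 1.88). Of the Paneth cell genes, Mmp7, whose protease activates defensins, differed by 2.26 ± 0.38 and Itln1, which encodes a lectin, by 1.20 ± 0.18. Limma called 0 genes in this comparison (661 at an unadjusted p under 0.05, fewer than expected if no gene differed). The adjusted p was 0.0526 for Dclk1 and Sh2d6, 0.167 for Avil, 0.292 for Itln1, 0.337 for Trpm5, 0.386 for Mmp7 and 0.505 for Neurog3 and Chgb.

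The count of 0 in this comparison depended on the fit. With the replicate as a block 5 genes were called: the pancreatic colipase gene Clps (2.34), the lipase-related gene Pnliprp2 (2.38), Dclk1 (adjusted p = 0.0416), and Sh2d6 and Trpm5 (both adjusted p = 0.0256). A fit with the array strip as a block called 1 gene, Sh2d6 (3.43, adjusted p = 0.0276), and Dclk1 (2.99) had an adjusted p of 0.0659. With the arrays centred on a common median 2 were called, Dclk1 (2.90) and Sh2d6 (3.35), both with adjusted p = 0.0486. The MR793 pair lay on strip 1 and the MR820 pair on strip 2, so the values per replicate given for this comparison are also the values within each strip. Without the array that stood apart 3 genes were called: the enteroendocrine transcription factor genes Nkx2-2 (2.16, adjusted p = 0.000573) and Insm1 (2.38, adjusted p = 0.0307), and the phospholipase gene Pla2g2f (2.05, adjusted p = 0.0307). The count was 4 without the Mex3a-low Lgr5-low array of MR793 and 4 without that of MR820. It was 10644 without the Mex3a-high Lgr5-high array of MR820, which leaves that population with the array that stood apart alone. Over the alternatives tried the adjusted p of Dclk1 ran from 0.000132 to 0.718 and that of Sh2d6 from 7.9e-05 to 0.718. Clps, Pnliprp2, Pla2g2f, Nkx2-2 and Insm1 fall outside the rule for naming genes and were named after their values were seen.

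The tuft cell list was higher in Mex3a-high than in Mex3a-negative Lgr5-high cells, with a median of 0.67 (0.90 in strip 1, 0.76 in strip 2) and 16 of 17 genes positive (camera adjusted p = 3.6e-12, and 0.287 with an estimated correlation). The Paneth cell list had a median of 1.04 (1.33 and 0.77, 8 of 10 genes positive, adjusted p = 1.9e-05, and 0.287 with an estimated correlation). The enteroendocrine list had 0.68 (0.77 and 0.24, 25 of 26 positive, adjusted p = 4.8e-06, and 0.37 with an estimated correlation). The secretory progenitor list had 0.37 (0.45 and 0.30, 12 of 14 positive, adjusted p = 0.000403, and 0.287 with an estimated correlation). Adjusted over the list alone, 9 tuft cell genes, 7 Paneth cell genes, 3 enteroendocrine genes and 3 secretory progenitor genes were higher. The goblet cell list had a median of 0.27 (0.55 and 0.23, adjusted p = 0.00206, and 0.403 with an estimated correlation), but its mean in MR820 was -0.11. Of its genes 4 were higher adjusted over the list alone. These medians were the same with the strip as a block, since each replicate's pair shares a strip. They were, without the array that stood apart, 0.83 for tuft, 0.71 for Paneth, 0.41 for enteroendocrine, 0.43 for secretory progenitor and 0.42 for goblet cell genes.

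The enterocyte list was lower in Mex3a-high than in Mex3a-negative Lgr5-high cells with the preset correlation, while the cell cycle lists differed mainly in the pair with the array that stood apart. The enterocyte list had a median of -0.64 (-0.57 in strip 1, -0.59 in strip 2), with 2 of 26 genes positive (camera adjusted p = 1.5e-05, and 0.403 with an estimated correlation). Krt20, a keratin gene of the differentiated epithelium, differed by -1.27 ± 0.49 and Mttp, which encodes a lipoprotein assembly protein, by -0.97 ± 0.32 (both adjusted p = 0.505). The mitosis list had a median of -0.54 (adjusted p = 7.3e-12, and 0.287 with an estimated correlation), with means of -1.04 in strip 1 and -0.10 in strip 2, and its median was -0.28 without the array that stood apart. The mitosis gene Hmmr differed by -1.09 ± 0.35 (-1.96 in MR793, -0.22 in MR820, adjusted p = 0.505). Also called were the mitochondrial respiration list (-0.33, adjusted p = 9.6e-12) and the fatty acid oxidation list (-0.50, adjusted p = 0.00102), at -0.59 and -0.96 in strip 1 and at -0.07 and 0.01 in strip 2. So were the DNA replication list (-0.27, adjusted p = 0.00055) and the mesenchymal list (0.28, adjusted p = 0.00206), at -0.65 and 0.64 in strip 1 and at 0.10 and -0.10 in strip 2. Their adjusted p ran from 0.37 to 0.546 with an estimated correlation. Without the array that stood apart DNA replication was at 0.11 and the mesenchymal list at -0.07. The intestinal stem cell list (-0.12, adjusted p = 0.203), the Wnt target list (0.03, adjusted p = 0.807, with a test that pointed down) and the ribosome biogenesis list (-0.21, adjusted p = 0.0506) were not called. They were at -0.29, -0.06 and -0.39 in strip 1 and at 0.11, 0.09 and 0.01 in strip 2. Without the array that stood apart they were at 0.15 (adjusted p = 0.0111), 0.13 and 0.04 (both adjusted p = 0.0847).

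Between Mex3a-high and Mex3a-low cells of the Lgr5-high gate no single gene passed the test, and the tuft cell and enteroendocrine lists were higher in Mex3a-high cells with the preset correlation and not with an estimated one. Dclk1 differed by 2.48 ± 0.32 (2.52 in MR793, 2.45 in MR820, limma adjusted p = 0.337), Sh2d6 by 2.60 ± 0.38 (adjusted p = 0.523) and Chgb by 3.67 ± 0.81 (adjusted p = 0.554). Of the enterocyte genes, the apolipoprotein genes Apoa1 and Apoa4 differed by 2.00 ± 0.55 and 2.64 ± 0.86 and Krt20 by 1.38 ± 0.49 (each adjusted p = 0.554). Limma called 0 genes (621 at an unadjusted p under 0.05, fewer than expected if no gene differed). It called 1, Nkx2-2 (1.78, adjusted p = 0.00312, also named after its value was seen), without the array that stood apart, 1 without either Mex3a-low Lgr5-low array, and 10379 without the Mex3a-high Lgr5-high array of MR820. The tuft cell list (0.62, adjusted p = 2.0e-09) and the enteroendocrine list (0.63, adjusted p = 2.9e-06, 26 of 26 genes positive) were called. So were the mitosis list (-0.46, adjusted p = 4.1e-08), the DNA replication list (-0.46, adjusted p = 2.9e-06) and the mitochondrial respiration list (-0.27, adjusted p = 4.6e-07). With an estimated correlation each of these 5 had adjusted p = 0.616. The mean of the mitosis list differed by -0.81 in MR793 and by -0.08 in MR820, and that of the DNA replication list by -0.93 and -0.01. Adjusted over the list alone 5 tuft cell genes and 2 enteroendocrine genes were higher. The enterocyte list (0.48, adjusted p = 0.00498, and 0.629 with an estimated correlation) was not called with the strip as a block (0.67, adjusted p = 0.192). In that fit the tuft cell, enteroendocrine, mitosis, DNA replication and mitochondrial lists were at 0.82, 0.64, -0.46, -0.64 and -0.36. The mesenchymal list was at 0.31 (adjusted p = 0.00772, and 0.701 with an estimated correlation) and at 0.47 with the strip as a block. It was at -0.12 without the array that stood apart, mitosis at -0.14, DNA replication at 0.07 and mitochondrial respiration at -0.00315, with a test that pointed up. The MR793 pair shared strip 1, so its values are those within a strip.

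Enterocyte genes were lower and Paneth cell genes higher in Mex3a-low than in Mex3a-negative cells of the Lgr5-high gate. The enterocyte list had a median of -0.85, with 1 of 26 genes positive (camera adjusted p = 1.2e-47, and 0.0223 with an estimated correlation) and mean changes of -1.44 in MR793, within strip 1, and -1.11 in MR820. Krt20 differed by -2.65 ± 0.49 (-2.73 in MR793, -2.57 in MR820), Apoa1 by -2.69 ± 0.55, the meprin gene Mep1b by -2.27 ± 0.58 and Clec2h, which encodes a lectin-like receptor, by -2.20 ± 0.51. The Paneth cell list had a median of 0.64, with 8 of 10 genes positive (adjusted p = 1.1e-12, and 0.0223 with an estimated correlation). Itln1 differed by 1.00 ± 0.18 and Mmp7 by 1.65 ± 0.38. Limma called 0 single genes (79 at an unadjusted p under 0.05, fewer than expected if no gene differed). The array that stood apart is in neither of these populations but widens the spread that all comparisons share. The absence of calls is therefore not evidence of no difference. Each gene named here had adjusted p = 1.00. Adjusted over the list alone 9 enterocyte genes were lower and 2 Paneth cell genes higher. The medians were, with the strip as a block, -0.91 for the enterocyte and 0.35 for the Paneth cell list. The estimated-correlation calls were lost without the array that stood apart (adjusted p = 0.233 for the enterocyte and 0.0715 for the Paneth cell list). Smaller shifts were those of the tuft cell (0.24, adjusted p = 9.3e-06), goblet cell (0.12, adjusted p = 8.6e-06, mean in MR820 -0.32), secretory progenitor (0.12, adjusted p = 0.000189) and mitochondrial lists (-0.07, adjusted p = 6.3e-05). They had adjusted p from 0.239 to 0.722 with an estimated correlation. With the strip as a block the mitochondrial list was at 0.03 (adjusted p = 0.459).

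Among Lgr5-low cells, enteroendocrine, tuft and Paneth cell genes were higher in Mex3a-high than in Mex3a-negative cells. The incretin hormone gene Gip rose by 6.43 ± 0.73, from 6.35 ± 0.38 to 12.78 ± 0.37 (6.43 in both replicates, limma adjusted p = 0.00121). Cpe, which encodes a prohormone-processing carboxypeptidase, rose by 5.57 ± 0.59 (adjusted p = 0.00083) and Tac1, the substance P precursor gene, by 5.21 ± 0.58 (adjusted p = 0.00118). The enteroendocrine transcription factor genes Neurod1, Isl1 and Pax4 rose by 3.43 ± 0.18, 4.04 ± 0.32 and 1.96 ± 0.26 (adjusted p = 3.2e-05, 0.000139 and 0.00344). Of the tuft cell genes, Dclk1 rose by 6.27 ± 0.32 (6.37 in MR793, 6.18 in MR820, adjusted p = 3.2e-05), Sh2d6 by 5.85 ± 0.38, the leukotriene synthesis gene Alox5ap by 5.52 ± 0.33 and Avil by 4.88 ± 0.28. Siglecf, which encodes a sialic acid-binding lectin, Spib, an Ets factor gene, and Kctd12 rose by 5.72 ± 0.56, 5.32 ± 0.48 and 5.28 ± 0.54. Of the Paneth cell genes, Mmp7 rose by 3.25 ± 0.38, Itln1 by 2.95 ± 0.18 and the defensin gene Defa21, whose paralogs may share its probes, by 5.36 ± 0.62 (6.81 and 3.91). Defa3, another defensin gene of the Paneth cell list, went the other way, by -0.76 (adjusted p = 0.0904), and was lower adjusted over the list alone. The cyclin-dependent kinase inhibitor gene Cdkn1c rose by 4.00 ± 0.27 (adjusted p = 4.9e-05). Cdkn1a differed by 2.01 ± 0.53 (adjusted p = 0.151, and 0.0444 with the replicate as a block). The 2 genes that fell were Slc23a4 (-0.87 ± 0.18, adjusted p = 0.0456), of a nucleobase transporter, and Lsm5 (-0.65 ± 0.13, adjusted p = 0.0494), of an RNA-binding complex.

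Limma called 295 of 17097 genes between these Lgr5-low populations, 293 higher and 2 lower, and 252 of the higher genes by more than 2-fold. The sign was the same in both replicates for all 295. The array that stood apart is in neither of these populations, so leaving it out keeps every change and alters only the shared spread. The count was 905 (694 higher, 211 lower) without the array that stood apart, with all 295 among them, and 533 in a fit of the Lgr5-low arrays alone. It was 165 without the Mex3a-high array of MR793 in this gate, 188 without the Mex3a-negative array of MR793, 174 without that of MR820, and 907 without the Mex3a-high Lgr5-high array of MR820. Of the 30 named genes called, 23 kept their call with each array left out. Neurog3 rose by 1.93 ± 0.35 (adjusted p = 0.0234, and 0.163 without the Mex3a-negative array of MR793). Dll4, a Notch ligand gene, rose by 1.54 ± 0.26 (adjusted p = 0.014, and 0.144 without the same array) and the mesenchymal list gene Vim by 3.18 ± 0.43 (adjusted p = 0.00387, and 0.0526 without the Mex3a-high array of MR793). Slc23a4 had an adjusted p of 0.469 without the Mex3a-high array of MR793 and Lsm5 of 0.426 without that of MR820. With the strip as a block Gip, Dclk1, Cpe and Tac1 were at 6.85, 6.51, 6.23 and 5.77. In that fit the calls of Neurog3 (1.61, adjusted p = 0.0555), Epb42 (1.13, adjusted p = 0.0574), Lyz2 (2.19, adjusted p = 0.0917), Slc23a4 (-0.93, adjusted p = 0.113) and Lsm5 (-0.59, adjusted p = 0.168) were lost. The MR793 pair shared strip 3, where Gip differed by 6.43.

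As lists, the enteroendocrine genes had a median change of 3.78 in this comparison, with 26 of 26 positive, 19 called and 26 higher adjusted over the list alone (camera adjusted p = 7.7e-65, and 0.00599 with an estimated correlation). The tuft cell genes had a median of 3.42, with 17 of 17 positive, 16 called and 17 higher adjusted over the list alone (adjusted p = 1.8e-66, and 0.00599 with an estimated correlation). The Paneth cell list was at 1.22 (3 called, 6 higher and 1 lower adjusted over the list alone, adjusted p = 9.6e-08) and the secretory progenitor list at 0.50 (3 called, 14 of 14 positive, adjusted p = 1.1e-09). Both had adjusted p = 0.0395 with an estimated correlation. Without the array that stood apart these estimated-correlation p values were 0.0575 for the enteroendocrine, tuft and Paneth cell lists and 0.145 for the secretory progenitor list. The mitosis list fell, with a median of -0.53 and 0 of 29 genes positive (adjusted p = 1.2e-16, and 0.114 with an estimated correlation), and 0 of its genes were called by limma with all arrays (11 without the array that stood apart). Its cyclin gene Ccna2 differed by -0.42 ± 0.12 (adjusted p = 0.217). DNA replication (-0.33, adjusted p = 4.1e-06), ribosome biogenesis (-0.25, adjusted p = 0.000175) and mitochondrial respiration (-0.24, adjusted p = 6.0e-08) were lower. They had 0 genes called and adjusted p from 0.446 to 0.466 with an estimated correlation. The immune list was at 0.18 (3 called, adjusted p = 0.000175, and 0.381 with an estimated correlation). Its called genes were Rac2 (3.43, limma adjusted p = 0.00192), Ptprc, the gene of the leukocyte antigen CD45 (1.83 ± 0.19), and the lysozyme gene Lyz2 (2.16 ± 0.41, adjusted p = 0.0302). The call of Lyz2 was lost without the Mex3a-high array of MR793. The medians were 4.15 for enteroendocrine, 3.77 for tuft, 1.35 for Paneth, 0.43 for secretory progenitor, -0.56 for mitosis and 0.11 for immune genes with the strip as a block.

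Several lists were not called between these populations. The enterocyte list had a median of 0.02 (adjusted p = 0.616) with means of -0.69 in MR793 and 0.86 in MR820. The intestinal stem cell list was at 0.10 (adjusted p = 0.148), Wnt targets at 0.10 (adjusted p = 0.277) and goblet cell genes at 0.10 (adjusted p = 0.117). The means of these 3 lists were 0.45, 0.37 and -0.26 in MR793 and -0.08, -0.06 and 0.40 in MR820. The reserve stem cell list was at 0.12 (adjusted p = 0.148), with 1 called gene, the homeobox gene Prox1 (2.96 ± 0.36). The CDK inhibitor list was at 0.12 (adjusted p = 0.158), with Cdkn1c called, and mesenchymal genes at 0.01 (adjusted p = 0.454), with Vim called. Red blood cell genes were at 0.05 (adjusted p = 0.135), with the membrane skeleton gene Epb42 called (1.12 ± 0.19, adjusted p = 0.014, and 0.147 without the Mex3a-negative array of MR820). Fatty acid oxidation genes were at -0.25 (adjusted p = 0.0765) and Notch pathway genes at 0.06 (adjusted p = 0.741, with a test that pointed down). Immediate early genes were at -0.02 (adjusted p = 0.851). With the strip as a block they were at 0.48 and called by camera (adjusted p = 0.00179).

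**Figure D1:**
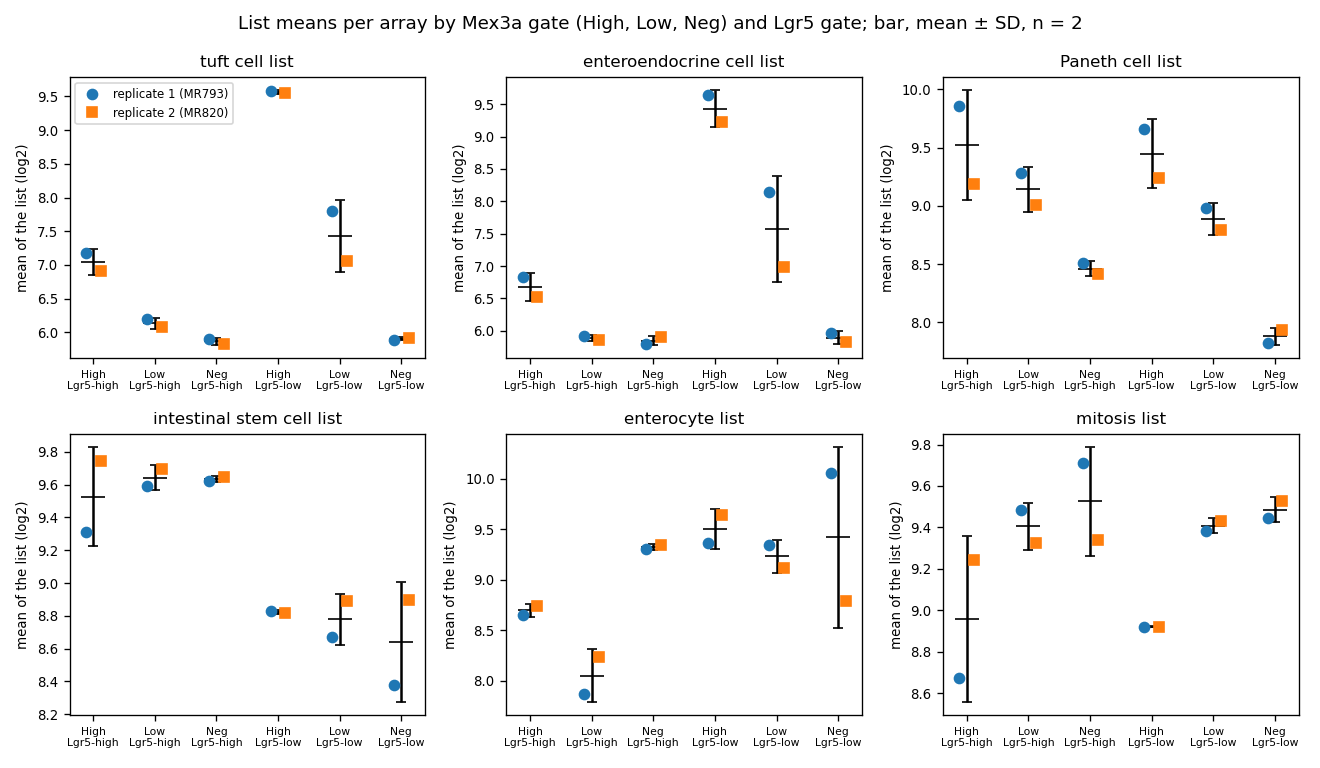
Mean RMA log2 level of 6 gene lists per array (vertical axis) by population (horizontal axis), with the mean ± SD of n = 2; the tuft cell list stands at 9.57 in Mex3a-high and 5.91 in Mex3a-negative cells of the Lgr5-low gate, and at 7.04 and 5.87 in the Lgr5-high gate.

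**Figure D2:**
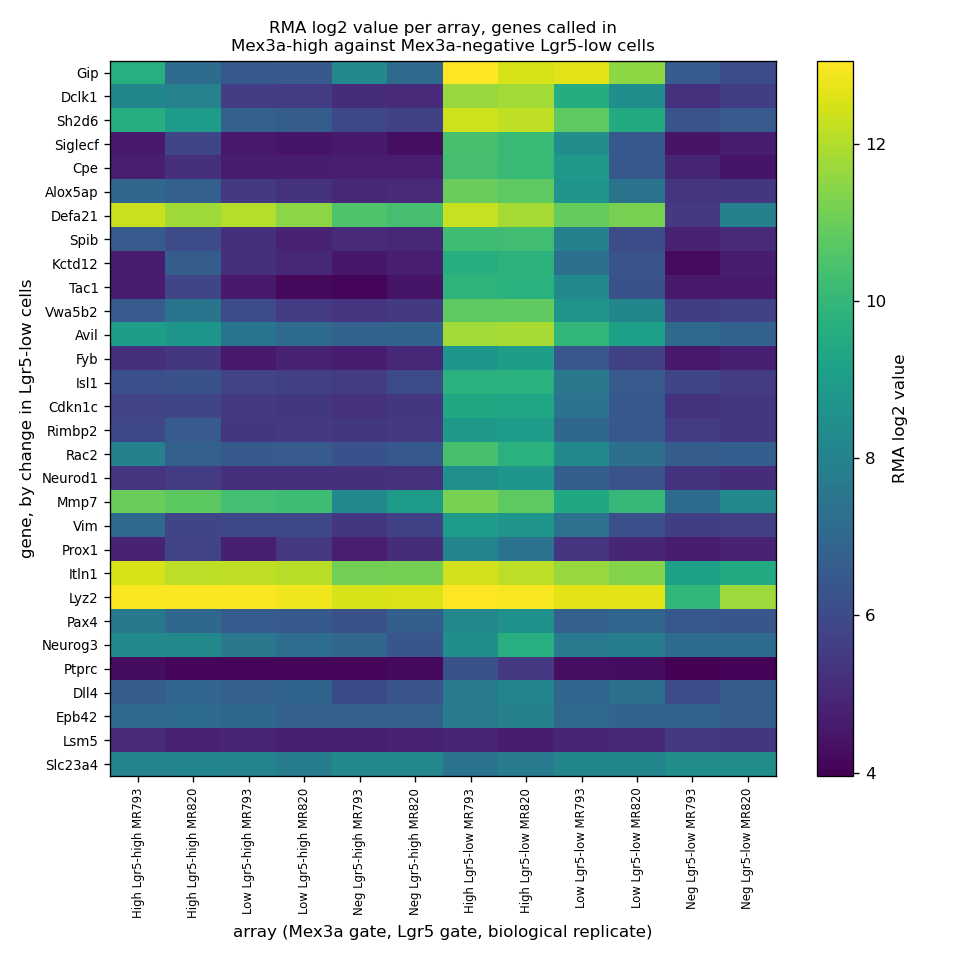
RMA log2 level (color) of the 30 named genes called between Mex3a-high and Mex3a-negative Lgr5-low cells (vertical) in each of the 12 arrays (horizontal); Gip averages 12.78 in Mex3a-high and 6.35 in Mex3a-negative cells of that gate.

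Mex3a-high cells of the Lgr5-low gate also had higher tuft cell and enteroendocrine levels than Mex3a-low cells. The glycogen phosphorylase gene Pygl rose by 3.36 ± 0.31 (limma adjusted p = 0.00124), with 2.81 within strip 3, which is MR793, and 3.90 within strip 2, which is MR820. The tuft cell list gene Fyb, which encodes an adaptor protein, rose by 2.83 ± 0.24 (2.32 and 3.34, adjusted p = 0.000932) and Dclk1 by 2.69 ± 0.32 (2.06 and 3.33, adjusted p = 0.00389). Neurod1 rose by 2.15 ± 0.18 (1.84 and 2.46, adjusted p = 0.000932) and Cdkn1c by 2.43 ± 0.27 (1.99 and 2.86, adjusted p = 0.00305). Spib rose by 3.25 ± 0.48 (adjusted p = 0.0138, and 0.123 without the Mex3a-high array of MR793). Kctd12 rose by 2.89 ± 0.54 (adjusted p = 0.0476, 0.0622 with the replicate as a block and 0.551 without the Mex3a-low array of MR820). Limma called 152 genes, all higher, 136 by more than 2-fold, and 91 with the dimmest genes left out. The enteroendocrine list had a median of 2.13 (1.69 within strip 3, 2.35 within strip 2), with 6 called and 22 of 26 higher adjusted over the list alone (camera adjusted p = 4.6e-45, and 0.0159 with an estimated correlation). Tuft cell genes had a median of 2.26 (1.87 and 2.61), with 15 called and 17 of 17 higher adjusted over the list alone (adjusted p = 1.6e-59, and 0.0155 with an estimated correlation). These estimated-correlation p values were both 0.132 without the array that stood apart. The mitosis list was at -0.43, and -0.45 within either strip, with 0 of 29 genes positive (adjusted p = 5.4e-18, and 0.163 with an estimated correlation). DNA replication was at -0.36 and ribosome biogenesis at -0.26 (adjusted p = 8.3e-08 and 4.4e-06, and both 0.433 with an estimated correlation). The Paneth cell list was at 0.79 (adjusted p = 0.00387, and 0.336 with an estimated correlation), 0.89 within strip 3 and 0.63 within strip 2.

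Arrays of the Lgr5-high gate are in neither of these populations, so leaving any of them out keeps every change and alters only the shared spread. The count of 152 moved with single arrays. It was 420 without the array that stood apart (all 152 among them), 419 without the Mex3a-high Lgr5-high array of MR820, 95 without either Mex3a-low and 94 without either Mex3a-negative array of the Lgr5-high gate. Within the Lgr5-low gate it was 54 without the Mex3a-high array of MR793, 94 without that of MR820 and 49 without the Mex3a-low array of MR820.

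Between Mex3a-low and Mex3a-negative cells of the Lgr5-low gate limma called 8 genes, all higher in Mex3a-low cells. Gip rose by 5.73 ± 0.73 (6.05 in MR793, which is the value within strip 3, and 5.42 in MR820, adjusted p = 0.0397). Sh2d6 rose by 3.72 ± 0.38 (adjusted p = 0.0172), Dclk1 by 3.58 ± 0.32 (adjusted p = 0.00724) and the fucosyltransferase gene Fut2 by 2.75 ± 0.29 (adjusted p = 0.0172). Vwa5b2 rose by 2.71 ± 0.32 (adjusted p = 0.0314), Alox5ap by 2.70 ± 0.33 (adjusted p = 0.0363), Avil by 2.60 ± 0.28 (adjusted p = 0.0181) and Itln1 by 2.16 ± 0.18 (adjusted p = 0.00724). None of the 8 calls held without the Mex3a-negative array of MR793 in this gate. The adjusted p was then 0.0907 for Itln1, 0.124 for Dclk1, 0.162 for Sh2d6 and Avil and 0.374 for Alox5ap. Without the Mex3a-low array of MR793 it was 0.596 for Gip, 0.454 for Vwa5b2 and 0.245 for Fut2. The 8 genes were, with the strip as a block, at 6.16 (Gip), 4.09 (Sh2d6), 3.82 (Dclk1), 2.95 (Fut2), 2.85 (Vwa5b2), 3.05 (Alox5ap), 2.80 (Avil) and 2.30 (Itln1), and 20 genes were called. With replicate and strip together the count was 2 (Gip and Fut2), and with quantile normalization again 3 (Itln1, Dclk1 and Fut2). The count was 1 without the Mex3a-low array of MR793 and 18 without that of MR820. It was 16 without either Mex3a-high Lgr5-high array, and 2 without the Mex3a-high Lgr5-low array of either replicate or any Mex3a-low or Mex3a-negative array of the Lgr5-high gate. Tuft cell genes were higher as a list, with a median of 1.32, 4 genes called and 11 higher adjusted over the list alone (camera adjusted p = 2.2e-66, and 0.00647 with an estimated correlation). So were the enteroendocrine list (1.43, 2 called, 14 higher adjusted over the list alone, adjusted p = 5.0e-63, and 0.00647 with an estimated correlation) and the Paneth cell list (0.35, 1 called, 3 higher adjusted over the list alone, adjusted p = 1.5e-11, and 0.0177 with an estimated correlation). The secretory progenitor list was at 0.52 with 14 of 14 genes positive (adjusted p = 5.7e-13, and 0.0184 with an estimated correlation). These 4 lists were at 1.51, 1.85, 0.45 and 0.31 with the strip as a block. Their estimated-correlation p was 0.0535 for the first 3 and 0.114 for secretory progenitors without the array that stood apart. The goblet cell list was at 0.30 with 18 of 19 genes positive (adjusted p = 8.2e-11, and 0.0545 with an estimated correlation).

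Averaged over the Mex3a gates, Lgr5-high cells had higher levels of single stem cell and Wnt target genes than Lgr5-low cells. Their levels of single enteroendocrine, tuft and goblet cell genes were lower. As lists, enteroendocrine and tuft cell genes differed little in Mex3a-negative cells, so their averaged falls came from the other Mex3a gates. Lgr5 rose by 2.61 ± 0.23 (2.57 in MR793, 2.65 in MR820, limma adjusted p = 0.000843), though it was used to isolate the cells. The estrogen receptor gene Esr1 rose by 1.31 ± 0.09 (adjusted p = 0.000663), the gastrokine gene Gkn3 by 1.57 ± 0.18 (adjusted p = 0.00314) and the urea transporter gene Slc14a1 by 1.43 ± 0.12 (adjusted p = 0.000843). The Wnt pathway feedback genes Axin2 and Rnf43 rose by 0.99 ± 0.11 and 1.20 ± 0.16 (adjusted p = 0.00266 and 0.00601). Gip (-2.88 ± 0.42, adjusted p = 0.01), Cpe (-2.74 ± 0.34) and the serotonin synthesis gene Tph1 (-2.52 ± 0.28) fell. So did Dclk1 (-2.50 ± 0.18), Hepacam2 (-2.71 ± 0.24) and Cdkn1c (-1.67 ± 0.15). In Mex3a-negative cells alone Gip ran the other way, at 7.67 in the Lgr5-high and 6.35 in the Lgr5-low gate. Dclk1 was at 5.07 and 5.45 in these cells, a smaller fall than the averaged one. Cdkn1c was at -3.47 in the Mex3a-high pair of MR820, a larger fall than the averaged one. Averaged over the Mex3a gates, the goblet cell genes Guca2a and Agr2 were each at -1.49 ± 0.20 (adjusted p = 0.00734 and 0.00752). Chgb was at -2.34 ± 0.47 (adjusted p = 0.0495), with an adjusted p of 0.0503 with the replicate as a block and of 0.184 without the Mex3a-low Lgr5-low array of MR793. Krt20 was at -1.66 ± 0.28 (adjusted p = 0.0235, and 0.104 without the Mex3a-negative Lgr5-high array of MR793).

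Limma called 236 genes between the Lgr5 gates, 43 higher and 193 lower in Lgr5-high cells, and 0 with the strip as a block, because only the Mex3a-high pair of MR820 shares a strip. In that fit Lgr5 was at 3.04 ± 0.43 (adjusted p = 0.262), Esr1 at 1.45 and Gip at -3.53 (both adjusted p = 0.176). Within strip 2 the differences were 2.60 for Lgr5, 0.93 for Esr1 and -5.33 for Gip. The difference between the Lgr5 gates cannot be told apart from a difference between strips by this test. With the replicate as a block 348 genes were called (81 higher, 267 lower). The count was 875 without the array that stood apart and 9323 without the Mex3a-high Lgr5-high array of MR820. In the Lgr5-high gate it was 114 and 106 without the Mex3a-low array of MR793 and of MR820, and 110 and 111 without the Mex3a-negative arrays in the same order. In the Lgr5-low gate it was 113 and 152 without the Mex3a-high arrays in the same order, 111 without the Mex3a-low array of MR793 and 122 without the Mex3a-negative array of MR793.

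As lists, intestinal stem cell genes were higher in Lgr5-high cells, with a median of 0.79, 10 called and 20 of 27 higher adjusted over the list alone (camera adjusted p = 4.7e-20, and 0.0525 with an estimated correlation). Wnt targets were higher by 0.48, with 8 called and 10 of 18 higher adjusted over the list alone (adjusted p = 7.1e-12, and 0.0315 with an estimated correlation). The stem cell and Wnt target lists share most of the Wnt target genes, among them Axin2, Rnf43, Sp5 and Tnfrsf19, so their results are not independent. Both also hold Lgr5, which was used to isolate the cells. The enteroendocrine list fell (-1.51, adjusted p = 2.6e-29), with 15 called and 23 of 26 lower adjusted over the list alone. So did the tuft cell list (-1.24, adjusted p = 4.2e-28), with 12 called and 15 of 17 lower adjusted over the list alone, and the goblet cell list (-0.70, adjusted p = 7.5e-15), with 7 called and 13 of 19 lower adjusted over the list alone. The last 3 lists each had adjusted p = 0.0315 with an estimated correlation. For all 5 it was 0.088 without the array that stood apart. With the strip as a block these medians were 0.82 (stem), 0.61 (Wnt), -1.08 (enteroendocrine), -0.98 (tuft) and -0.74 (goblet). Within strip 2, in the Mex3a-high pair of MR820, they were 0.84, 0.57, -2.61, -2.69 and -0.78. In Mex3a-negative cells the mean of the tuft cell list was 5.91 (MR793) and 5.83 (MR820) in the Lgr5-high gate. It was 5.89 and 5.92 in the Lgr5-low gate. The enteroendocrine list was at 5.80 and 5.90 against 5.96 and 5.82 in these cells. Its averaged fall and that of the tuft cell list thus came from the Mex3a-high and Mex3a-low gates. The enterocyte list (-0.73, 1 called, 12 lower adjusted over the list alone, adjusted p = 2.8e-10, and 0.188 with an estimated correlation) was at -0.58 with the strip as a block and -0.83 within strip 2. Mitochondrial respiration (-0.21, adjusted p = 3.0e-10) and fatty acid oxidation genes (-0.34, adjusted p = 0.000122) had adjusted p of 0.298 and 0.432 with an estimated correlation, and were at -0.04 and -0.09 with the strip as a block. The CDK inhibitor list was at -0.18, with Cdkn1a and Cdkn1c called (adjusted p = 0.00185, and 0.169 with an estimated correlation), and at -0.14 with the strip as a block. The mitosis (0.02, adjusted p = 0.634), Notch pathway (0.09, adjusted p = 0.259), reserve stem cell (0.22, adjusted p = 0.394) and Paneth cell lists (0.24, adjusted p = 0.0645) were not called.

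The rise from Mex3a-negative to Mex3a-high cells was smaller in the Lgr5-high than in the Lgr5-low gate for 68 genes by limma, and larger for 0. The difference of the changes was -3.17 ± 0.26 for Neurod1 (-3.06 in MR793, -3.27 in MR820, adjusted p = 0.00234) and -3.74 ± 0.35 for Fyb (adjusted p = 0.00295). It was -4.04 ± 0.43 for Pygl (adjusted p = 0.0054) and -3.51 ± 0.37 for Cdkn1c (adjusted p = 0.0054). With the strip as a block these were -3.22, -3.84, -4.24 and -3.76, and no strip holds all 4 populations of a replicate. The enteroendocrine list was at -2.94, and at -3.20 with the strip as a block, with 0 of 26 genes positive (camera adjusted p = 4.1e-37, and 0.0262 with an estimated correlation). The tuft cell list was at -2.67, and at -2.79 with the strip as a block, with 0 of 17 positive (adjusted p = 1.5e-41, and 0.0262 with an estimated correlation). For both the estimated-correlation p was 0.112 without the array that stood apart. The count of 68 was 141 with the strip as a block and 32 with the dimmest genes left out. It was 160 without the array that stood apart and 8315 without the Mex3a-high Lgr5-high array of MR820. It was 31 without the Mex3a-high Lgr5-low array of MR793, 24 and 23 without the Mex3a-negative Lgr5-low arrays of MR793 and MR820, and 23 and 18 without the Mex3a-negative Lgr5-high arrays in the same order.

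**Figure D3:**
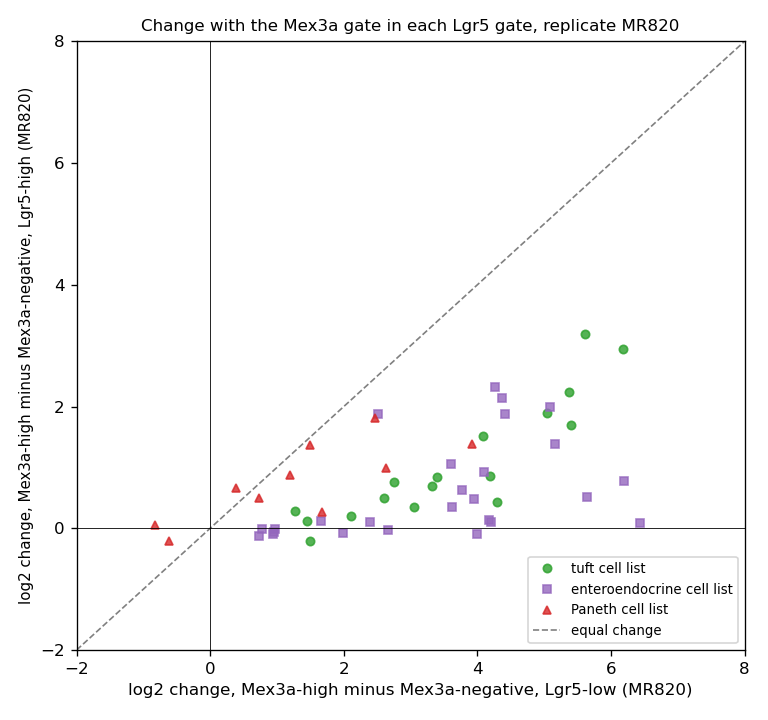
Change from Mex3a-negative to Mex3a-high cells of MR820 (log2) in the Lgr5-low gate (horizontal) and in the Lgr5-high gate (vertical) for the tuft cell, enteroendocrine and Paneth cell lists, 1 point per gene; the change is larger in the Lgr5-low gate for 17 of 17, 26 of 26 and 7 of 10 genes.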

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

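Of the tests in this part, the signal loss of the Mex3a-high Lgr5-high array of MR793, both versions of the carry-over ratio and the changes in MR820 alone were chosen after the results were seen; the genomic DNA, stromal and leukocyte tests were written before theirs.

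The change from Mex3a-negative to Mex3a-high cells differed between the Lgr5 gates by a test of the difference itself. This held for 68 genes, for 15 named genes and, with the preset correlation, for 5 lists. A negative value means a smaller rise in Lgr5-high cells. Of the tuft cell genes, the difference was -3.70 for Alox5ap, -3.74 for Fyb, -2.67 for Il17rb and -3.29 for Rgs13. Of the enteroendocrine genes, it was -3.17 for Neurod1, -3.66 for Isl1, -2.67 for Rimbp2, -3.51 for Vwa5b2 and -5.30 for Cpe. It was -3.51 for Cdkn1c, -1.75 for Itln1, -1.77 for Ptprc, -4.04 for Pygl, -4.01 for Spib and -4.92 for Siglecf (adjusted p = 0.0364; 0.0533 with the replicate as a block). Of these 15 genes 4 kept their call with each array left out; the highest adjusted p was 0.253 for Spib and 0.226 for Siglecf, both without the Mex3a-negative Lgr5-high array of MR793.

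As lists, the enteroendocrine genes differed by -2.94 and the tuft cell genes by -2.67, both with an estimated correlation too (adjusted p = 0.0262), though not without the array that stands apart (adjusted p = 0.112). The enterocyte list (-0.65; means of 0.05 in MR793 and -1.46 in MR820; adjusted p = 0.000195), the CDK inhibitor list (-0.37, adjusted p = 0.0199) and the immune list (-0.0909, adjusted p = 0.0157) were called with the preset correlation, with 0.772, 0.577 and 0.772 with an estimated one.

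The Mex3a-high Lgr5-high array of MR793 stands apart from the other 11, and loss of signal across genes in that library is a candidate explanation. Genes with a mean over 8 in the other Lgr5-high arrays were taken. Of these, 33.5% lie more than 1 below that mean in this array, against 0.0768% to 0.401% in the others. The share counts falls only, so it cannot tell loss of signal from a wider scatter in both directions. Stromal cells in the sample could contribute. The median deviation of 18 mesenchymal and endothelial genes, 0.69, lies at percentile 99.4 of random lists of the same brightness. Sparc was at 1.53, Vim at 1.31 and Col3a1 at 1.05 above the other arrays. Genes of the random lists were drawn separately, so the percentile does not allow for genes that move together. A share of genomic DNA cannot be told apart from none: 23 genes of sex chromosome families deviated by a median of 0.37, at percentile 96.8 of such lists, inside the central range of random lists. A biological difference of this sample stays open and untested, because the population has 1 other array.

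Secretory genes were higher in Mex3a-high than in Mex3a-negative Lgr5-high cells, and carry-over of Mex3a-high Lgr5-low cells could bring such genes in. It cannot be told apart from expression in the cells themselves. An even sample of those cells would bring the same fraction of every gene, and in MR820 the median fraction was 0.155 for 5 early transcription factor genes and 0.0220 for 12 hormone and granule genes, a ratio of 7.05. The 5 early genes (Neurog3 0.341, Insm1 0.187, Nkx2-2 0.155, Pax4 0.0882, Neurod1 0.0264) were chosen after values were seen, so this ratio decides nothing. The 10 called of 11 transcription factor genes gave a median of 0.0573 and a ratio of 2.60, with Isl1 at 0.00803, Pax6 at -0.0170, Lmx1a at -0.134 and Etv1 at -0.00419. The 16 tuft cell genes had a median of 0.0742 (0.0220 for Fyb to 0.175 for Cd24a). These fractions cover the genes called between Mex3a-high and Mex3a-negative Lgr5-low cells, which leaves out 8 hormone and granule genes, among them Chgb (adjusted p = 0.0534) at 0.199, the tuft cell gene Plcb2 at -0.0792 and the factor gene Mnx1 at 0.526. The array that stands apart is argued against as the whole cause by MR820 alone, which does not use it. There the enteroendocrine list differed by a mean of 0.631 (18 of 26 genes higher, limit of random lists 0.103). The tuft cell list differed by 1.08 (16 of 17, limit 0.121). Genes of the random lists were drawn separately, so these limits do not allow for genes that move together. Each value is a difference of 2 arrays, so its spread between arrays is not known. Carry-over of those cells or of a subset of them, and early secretory cells within the Mex3a-high Lgr5-high population, stay open.

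Leukocyte genes were higher in Mex3a-high than in Mex3a-negative Lgr5-low cells, Ptprc by 1.83 and Rac2 by 3.43. Rac2 is not among the 13 markers tested here. Leukocytes in the isolated population would bring lineage markers with Ptprc, but 13 such markers had a median change of 0.17 (95% bootstrap range 0.00700 to 0.34), 0.0926 of that of Ptprc, with 1 called, Lyz2, which Paneth cells express too; H2-Ab1 was at -0.19 and Cd74 at -0.25. As a set these markers did not rise as Ptprc did, but the test cannot decide against a mixture of leukocytes. H2-Aa, H2-Ab1 and Cd74 averaged 9.99, 11.69 and 10.47 in Mex3a-negative Lgr5-low cells, where a small share of leukocytes would show little. Cd3d, Cd3e, Cd3g and Nkg7 averaged 4.99 to 5.55 there. That is below the array medians of 5.83 to 6.04, where differences are compressed. The granzyme genes Gzma and Gzmb were at 1.10 and 0.54 (adjusted p = 0.79 and 0.715), with Cd3e at 0.15 and Cd8a at 0.00700, so a contribution of granzyme-expressing lymphocytes stays open. Expression of Ptprc in tuft cells may explain it too, a hypothesis that was not tested here.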

How the results depend on the processing

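Camera without the array that stood apart (the Mex3a-high Lgr5-high array of MR793) was chosen after that array was seen; the other alternatives were planned. Comparisons are written high-negative, high-low and low-negative for the Mex3a gates, then the Lgr5 gate. Where no cause is given, the cause was not tested.

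The replicate as a block gave 5 calls for high-negative Lgr5-high, and the other counts (0, 0, 347, 168, 11, 348 and 83 in the order of the report) lay within 1.5 times. Of 108 calls of named genes it ended 3, Kctd12 (high-low Lgr5-low), Chgb (Lgr5 gates) and Siglecf (difference between gates), and changed no other call among them.

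The strip as a block gave 1 call for high-negative Lgr5-high, 20 for low-negative Lgr5-low, 0 between the Lgr5 gates and 141 for the difference between gates; with the replicate too, 2 for low-negative Lgr5-low and 0 between the Lgr5 gates. The loss between the Lgr5 gates follows from the layout, in which 1 pair shares a strip. Centring gave 2 for high-negative Lgr5-high, quantile normalization 3 for low-negative Lgr5-low, and the arrays of the Lgr5-low gate alone 533 for high-negative. Leaving out the dimmest genes gave 91 for high-low Lgr5-low and 32 for the difference between gates: fewer genes are tested, and dim genes are limited by their signal over background.

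Leaving out each array in turn gave 0 to 10644 calls for high-negative, 0 to 10379 for high-low and 0 to 0 for low-negative in the Lgr5-high gate, 165 to 907, 49 to 420 and 0 to 18 in the Lgr5-low gate, 106 to 9323 between the Lgr5 gates and 18 to 8315 for the difference. The counts of 10644, 10379, 9323 and 8315 come without the Mex3a-high Lgr5-high array of MR820, which leaves the array that stood apart as the only one of its population and out of the spread. Lists called by camera without that array numbered 13, 7, 10, 9, 8, 10, 15 and 9 in the order of the report, against 11, 7, 10, 9, 11, 12, 11 and 5 with it. With an estimated correlation and all arrays they numbered 0, 0, 2, 4, 2, 4, 4 and 2, and without that array 0 in each of the 8 comparisons.

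Of the lists called with all arrays or in the alternative, these changed the direction of their test without the array that stood apart. For high-negative Lgr5-high they were intestinal stem cell (0.15), DNA replication (0.11) and mesenchymal (-0.0700). For high-low Lgr5-high they were reserve stem cell (0.16), DNA replication (0.0711), mitochondrial respiration (its median stayed negative at -0.00315) and mesenchymal (-0.12). Between the Lgr5 gates it was DNA replication (0.19). For the difference they were mitochondrial respiration (0.15) and mesenchymal (-0.10). With the strip as a block they were ribosome biogenesis (0.12) and mitochondrial respiration (0.0305) for low-negative Lgr5-high, immediate early (0.48) for high-negative Lgr5-low, fatty acid oxidation (0.0237) for low-negative Lgr5-low, and DNA replication (0.22), immune (-0.17), mesenchymal (-0.13) and immediate early (0.22) between the Lgr5 gates. Of the other list results over these alternatives 809 were called or not called as before, 36 gained and 89 lost a call. Lists called in neither fit are among the 809 even where their median turned. An example is ribosome biogenesis for high-negative Lgr5-high, whose median turned positive without the array that stood apart.

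Of 108 calls of named genes 64 kept their call with each array left out, and 0 changed sign under any alternative. The strip as a block ended 43, replicate and strip together 54, quantile normalization 12, centring 3, probe set means 3, leaving out dim genes 3 of 90, no variance trend 11, and a fit of a single Lgr5 gate 7 of 55.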

Other observations

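The test of other splits was written before its result was seen, and the values of the lists below were chosen after they were seen. Immediate early and dissociation response genes differed between the replicates more than between the populations. The mean of this list was 9.74 to 9.95 in 5 arrays of MR793 and 9.19 in the array that stood apart, against 8.69 to 8.92 in the 6 arrays of MR820. Fos, a gene of the AP-1 transcription factor, was at 12.4 to 12.5 in those 5 arrays and 11.6 to 11.8 in MR820, and Egr1, a zinc finger transcription factor gene, at 12.2 to 12.3 and 11.3 to 11.6. In the array that stood apart Fos was at 11.2 and Egr1 at 11.5. In the fit without a block, no comparison of the populations called this list with all arrays. With the strip as a block camera called it for low-negative Lgr5-high (-0.29, adjusted p = 0.0359) and high-negative Lgr5-low (0.48, adjusted p = 0.00179). It was also called for low-negative Lgr5-low (0.47, adjusted p = 2.3e-07), between the Lgr5 gates (0.22, adjusted p = 0.00295) and for the difference (-0.65, adjusted p = 0.00147).

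Within the Lgr5-low gate the tuft and enteroendocrine lists had their middle level in Mex3a-low cells. The tuft cell list averaged 9.57 ± 0.03 (SD, n = 2) in Mex3a-high, 7.43 ± 0.53 in Mex3a-low and 5.91 ± 0.02 in Mex3a-negative cells, and the enteroendocrine list 9.43 ± 0.29, 7.57 ± 0.82 and 5.89 ± 0.10. The Paneth cell list averaged 9.45 ± 0.30, 8.89 ± 0.14 and 7.88 ± 0.08 in that gate and 9.52 ± 0.47, 9.14 ± 0.19 and 8.46 ± 0.06 in the Lgr5-high gate. Enterocyte genes had their lowest level, 8.05 ± 0.26, in Mex3a-low Lgr5-high cells.

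The number of genes called between Lgr5-high and Lgr5-low cells was compared with other splits of the 12 arrays that keep the Mex3a gates balanced. Of 100 splits drawn from 108, 1, the real one, called as many as 236, and the highest other called 139. The other splits mix Lgr5-high and Lgr5-low arrays within a group, which widens their spread and lowers their counts. The comparison therefore does not exclude chance by itself. The split that called 139 keeps the real Lgr5 labels in 2 of the 3 Mex3a gates. Splits that keep them in at most 1 gate called up to 36. Of the 100, 32 part as many replicate pairs as the real one, and 139 is the highest of the others there too. The splits do not separate the Lgr5 gates from the strips.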
